A study of Mus musculus with 20 samples.

How the data were processed

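The series holds 20 RNA-seq libraries, each from the liver of 1 male mouse on a western diet treated daily for 16 days, per the labels. The labels name control, glucagon, T3 and glucagon with T3, and a 5th set of libraries coded Cp, which was taken as the glucagon/T3 hybrid by elimination. Each group has 4 libraries, and the mice, not the reads, are the replicates. Doses and times of tissue collection are not given in the sources used here.

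Total RNA was extracted with a Qiagen kit and libraries were made with a Lexogen kit, per the labels' protocols. The values are raw counts per gene symbol, made with HTSeq on mm10 per the submitters' processing notes, which give no version, and the aligner, annotation and strand setting are not given in the sources used here. Counts for the same 13319 symbols are listed in every library. Each symbol reaches at least 20 counts in 1 or more libraries, so rarer genes cannot be studied, and 12 symbols had turned into dates and were left as they stand. Of the symbols 12113 matched GENCODE M21 names on GRCm38, which gave the positions of 160 of the 165 genes named in these texts. No Ensembl identifiers were given, so matching was by name alone.

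Library totals ran from 6091917 to 23195658 counts. The labels place control, glucagon, combination and hybrid replicates 1 to 4 in sequencing lanes 1 to 4 and all T3 replicates in lane 5. Replicate number therefore marks the lane in 16 libraries and marks no lane in the T3 group. Whether the numbers pair the libraries was checked: over pairs of groups that share lanes, the correlation of same-numbered libraries after removal of group means ran from -0.318 to 0.462. Between lanes 1 to 4, 3 of 12896 genes differed at an adjusted p under 0.05 and 1025 at an unadjusted p under 0.05 (edgeR). The first 4 principal components of log2 CPM held 29.6%, 16.8%, 12.6% and 9.5% of the variance.

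Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 12907 genes and dropped 412. Normalisation was by TMM, and all 20 libraries entered a quasi-likelihood fit with 5 group means (15 residual and 5 prior degrees of freedom). The common dispersion was 0.077, a biological coefficient of variation of 27.8%. The 9 contrasts were each treatment against control, hybrid against combination, glucagon and T3, combination against glucagon, and the departure of the combination from the sum of the glucagon and T3 effects. The p values were adjusted by Benjamini-Hochberg within a contrast, and genes under 0.05 were called.

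For gene groups, 28 lists were fixed before the data were examined, 22 of pathways and liver functions and 6 of cell types, with at least 5 tested members each. They were tested with camera on log2 CPM (prior count 2) with its preset inter-gene correlation of 0.01, adjusted over the 28 lists within a contrast, and beside it with the correlation estimated from the data and with fry. Counts of members that rose or fell used the adjustment over all genes, and again an adjustment over the list alone. Lists of 20 skeletal muscle, 20 interferon response and 10 core clock output genes were written after the data were seen.

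Genes were named by a rule set together with the lists. It took up to 6 genes with the highest and 6 with the lowest change among called genes with a mean of at least 20 CPM and with no overlap between the libraries compared (no overlap was asked for additivity), leaving out predicted genes. It added the 3 members of smallest p of the 5 lists with the smallest camera p, and of any other list described, and a panel that included Gcgr, Thrb, Dio1, Thrsp, Pck1, Cyp7a1 and Fgf21. Results of some genes that the rule names are not reported here. Errors are standard errors of the log2 change, and SD for CPM.

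For agreement between effects against the same controls, correlation and covariance across genes were set beside 100 simulations of unchanged groups and beside 6 ways of splitting the controls in pairs. The simulations first used a spread shared by the groups, which gave r = 0.497, 0.498 and 0.477 for hybrid with combination, glucagon and T3. Each group's own spread was used instead after that result was seen, and those values are reported.

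The fit was tested on simulated counts for the hybrid against control. Of 100 genes changed by log2 1, 49% were recovered, and of 100 changed by log2 2, 94%, with 5 unchanged genes among 148 calls (3.4%). With the cAMP-CREB list raised by log2 1, camera gave an adjusted p of 7.66e-30 for it and called 1 of the 27 other lists. These simulations used a spread shared by the groups and drew genes independently. They therefore do not show the error rate under the wider spread of the controls or with correlated genes.

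Alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone, replicate number as a block, and each library left out in turn. A fit without control 2 and glucagon 3, which hold the largest shares of skeletal muscle transcripts, was added after seeing the data. It kept hybrid 4 (0.0799% of counts) and combination 4 (0.0412%), which also stood apart from their groups in that share. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.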

Results

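Liver RNA was sequenced from 20 male mice kept on a western diet and treated daily for 16 days, 4 mice in each of 5 groups. The groups were control, glucagon (the pancreatic hormone that raises hepatic glucose output), T3 (triiodothyronine, the active thyroid hormone), glucagon and T3 given together (called combination here), and a single molecule that joins glucagon and T3 (called hybrid here). Reads per gene were counted for 13319 gene symbols, and total counts ran from 6091917 to 23195658 per library. Mean totals were 16918458 ± 5190829 (SD, n = 4) in control, 16672813 ± 3456980 in glucagon, 7021746 ± 778879 in T3, 12528310 ± 2067640 in combination and 12975138 ± 4269721 in hybrid, so the T3 libraries were the shallowest. Below, a gene is called changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test (Benjamini-Hochberg over 12907 genes). Changes are given as log2 ± SE, and levels as normalised CPM (counts scaled to library size) ± SD with n = 4. Single genes are ranked only among called genes with a mean of at least 20 CPM in the groups compared and, except for additivity, with no overlap between their libraries. Predicted genes are left out of this ranking. These are the ranked genes below, and members of lists can lie beyond them.

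The livers were not alike within groups. The biological coefficient of variation was 43.2% among the controls and between 18.9% and 25.8% in the other groups. Control 2 held 0.111% of its counts in 20 skeletal muscle genes and glucagon 3 held 0.342%, against at most 0.0799% in the other 18 libraries. Among those, hybrid 4 held 0.0799% and combination 4 held 0.0412%, and both stayed in the fits without control 2 and glucagon 3. Control 2 also had a mean of 6.27 log2 CPM over 20 interferon response genes, against 2.74 to 2.96 in the other controls, and means of 2.9 and 5.28 for cell cycle and macrophage genes, against 1.14 to 1.46 and 3.66 to 5.02. Its means were also the highest of the controls for cholangiocyte genes (4.37 against 2.36 to 2.92), stellate cell and fibroblast genes (5.81 against 3.82 to 4.67) and lymphocyte and granulocyte genes (2.53 against 1.37 to 2.17). Values without control 2 and glucagon 3 are therefore given for each list call that ended without them, and for some counts. All T3 libraries ran in sequencing lane 5, while each replicate number of the other groups ran in its own lane, 1 to 4. For single genes, comparisons with the T3 group cannot be told apart from a lane difference, and no value within lanes exists for them.

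Glucagon was set against control to ask what the hormone alone does to the liver, and it raised the early target genes of the cAMP-CREB pathway, the signalling route of the glucagon receptor. Nr4a3 (an orphan nuclear receptor) went from 0.433 ± 0.206 to 158 ± 27.8 CPM, a change of 8.50 ± 0.43, and Nr4a2 rose by 5.78 ± 0.28. Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, went from 10.8 ± 2.05 to 178 ± 20.6 CPM (4.04 ± 0.20). Of the 19 measured genes of this list, 13 rose and 0 fell, and 13 rose when adjusted over the list alone. The list test (camera) gave an adjusted p of 2.65e-14, and adjusted p = 0.00768 with an estimated correlation.

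Genes of amino acid breakdown and of glucose production rose with it. In the amino acid catabolism and urea cycle list 13 of 34 genes rose and 1 fell (15 and 2 adjusted over the list alone), among them Slc38a2, an amino acid transporter (2.60 ± 0.20), Got1, an aspartate aminotransferase (3.56 ± 0.31, from 311 ± 173 to 3670 ± 287 CPM), and Agxt, an alanine-glyoxylate aminotransferase (3.27 ± 0.31). Its camera adjusted p was 1.22e-07, and adjusted p = 0.391 with an estimated correlation. Of 19 gluconeogenesis genes 8 rose and 1 fell (the same numbers adjusted over the list alone), including G6pc, glucose-6-phosphatase, by 1.82 ± 0.23. Pck1, which encodes the rate-controlling enzyme of gluconeogenesis, went from 1690 ± 774 to 5760 ± 674 CPM (1.77 ± 0.28). The gluconeogenesis list had a camera adjusted p of 0.000204, and adjusted p = 0.0791 with an estimated correlation. In the mitochondrial respiratory chain list 7 of 36 genes rose and 0 fell (7 and 0 adjusted over the list alone), with small changes in Ndufv1 (0.71 ± 0.16), Uqcrfs1 (0.59 ± 0.15) and Cox6a1 (0.45 ± 0.14). That call had a camera adjusted p of 0.00255, ended without control 2 and glucagon 3 (0.0632, with 3 genes higher), and had adjusted p = 0.691 with an estimated correlation. Cox6a1 was no longer called without control 1 (0.0514), glucagon 1 (0.0625), glucagon 2 (0.0554) or glucagon 4 (0.0517).

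Macrophage markers were lower after glucagon: 17 of 24 fell and 0 rose (20 and 0 adjusted over the list alone), and 9 fell without control 2 and glucagon 3. Cybb, a subunit of the phagocyte oxidase, changed by -1.21 ± 0.25, Lyz2 (lysozyme) by -1.53 ± 0.32 and Mpeg1 by -1.52 ± 0.33. The list's camera adjusted p was 1.67e-05, and adjusted p = 0.597 with an estimated correlation. Of 25 bile acid genes 5 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0378, and adjusted p = 0.811 with an estimated correlation), and 8 fell without control 2 and glucagon 3. Those that fell included Nr1h4, the bile acid receptor (-1.77 ± 0.29), its target Nr0b2 (-2.32 ± 0.43) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, which went from 95.5 ± 19.5 to 20.1 ± 19.3 CPM (-2.26 ± 0.45). Of 24 thyroid hormone responsive genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), with Ppargc1a, Slc16a10, a carrier of aromatic amino acids (1.70 ± 0.17), and Bcl3 (1.84 ± 0.36) ahead (camera adjusted p = 0.00315, and adjusted p = 0.258 with an estimated correlation).

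The highest changes of ranked genes besides Nr4a2 and Nr4a3 were in Tas1r2, a sweet taste receptor subunit (8.72 ± 0.51), Akr1b7, an aldo-keto reductase (6.57 ± 0.74), BC057022 (6.21 ± 0.42) and Dos (4.87 ± 0.38). The lowest of them were in Rgs16, a regulator of G protein signalling (-4.75 ± 0.84), Arrdc3, an arrestin-like protein (-4.35 ± 0.33), and 4 interferon-induced genes. These were Ifit1 (-4.20 ± 0.89), Ifi44 (-3.79 ± 0.91), Usp18 (-3.72 ± 0.83) and Rsad2 (-3.31 ± 0.84). Without control 2 the interferon-induced genes changed less, with Ifit1 at -1.62 (edgeR adjusted p = 0.0179), Usp18 at -1.47 (0.037), Ifi44 at -1.18 (0.123) and Rsad2 at -0.50 (0.381), so the calls of Ifi44 and Rsad2 ended, and without control 2 and glucagon 3 that of Usp18 did (0.0821). With the lane as a block Ifi44 (0.0548) and Rsad2 (0.106) were not called either. The changes of Gcgr (-0.31 ± 0.22), Thrb (0.00 ± 0.18), Dio1 (0.33 ± 0.30) and Thrsp (-0.45 ± 0.56) were not called. The hormone Fgf21 changed by 0.19 ± 0.70 and was not called, but changed by 2.35 without control 2, in which it stood at 48.8 CPM (edgeR adjusted p = 0.00305).

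edgeR called 2732 genes between glucagon and control, 1191 higher and 1541 lower. A fit of these groups alone called 976, and leaving out 1 library at a time gave 1988 to 3760.

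**Figure D1:**
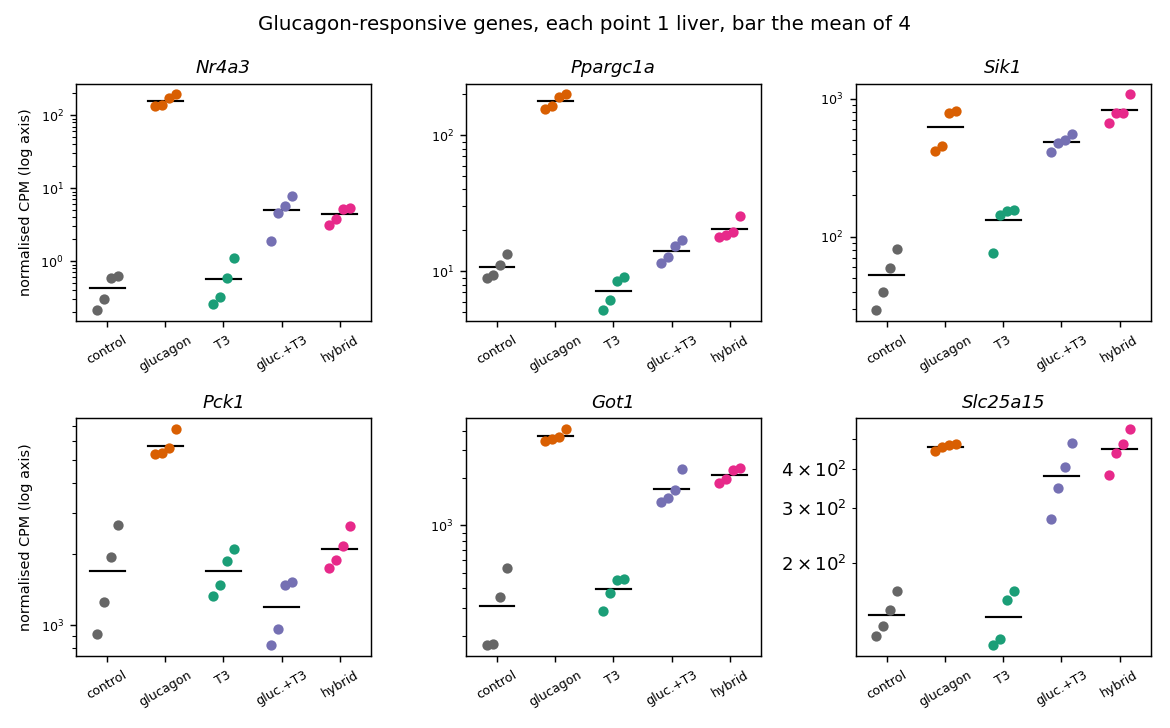
Normalised CPM (log axis) of 6 genes that respond to glucagon in the 5 treatment groups, each point 1 liver and each bar the mean of 4. Ppargc1a averaged 178 CPM after glucagon alone and 14.1 and 20.4 CPM after combination and hybrid, while Slc25a15 averaged 472, 379 and 463 CPM.

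T3 was set against control to ask for the effect of the thyroid hormone alone, and the liver's sex-biased genes moved from the male towards the female pattern. Of 20 male-biased genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), led by Cyp4a12a, a fatty acid hydroxylase, which went from 48.8 ± 29.4 to 0.263 ± 0.197 CPM (-7.49 ± 0.66), with Cyp4a12b (-7.04 ± 0.85) and Keg1 (-3.10 ± 0.33). Of 14 female-biased genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), among them Cyp17a1, steroid 17-alpha-hydroxylase, from 29.3 ± 11.7 to 387 ± 138 CPM (3.72 ± 0.36), the transcription factor Cux2 (6.37 ± 1.15) and Cyp3a44 (4.44 ± 0.82). Camera gave adjusted p = 0.000514 for each of these lists, and adjusted p = 0.794 with an estimated correlation for each. The mean of Cyp4a12a after T3 lies under the level of 3 counts in these libraries (0.375 to 0.49 CPM), so the size of its change is uncertain. Reads of the Cyp3a, Cyp4a, Cyp2c, Cyp2d, Ces, Ugt, Sult, Gst, Mup and Serpina3 families can be shared between near-identical copies, so values of their single members are uncertain throughout.

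Drug-metabolising and bile acid genes fell. Of 35 drug metabolism genes 17 fell and 2 rose (19 and 3 adjusted over the list alone), with Ephx1, the microsomal epoxide hydrolase (-1.5 ± 0.18), and Cyp3a11 (-2.46 ± 0.38) lower and Por, the electron donor of cytochromes P450, higher (1.49 ± 0.24). The camera adjusted p was 0.00119, and adjusted p = 0.794 with an estimated correlation. Of 25 bile acid genes 8 fell and 0 rose (9 and 1 adjusted over the list alone), including the transporter Abcc3 (-2.72 ± 0.24), Scp2 (-1.98 ± 0.24) and Akr1c6 (-1.85 ± 0.37, and -0.96 without control 1), with a camera adjusted p of 0.00374 and adjusted p = 0.794 with an estimated correlation. Lipid synthesis genes fell as well: 9 of 24 cholesterol synthesis genes fell and 1 rose (9 and 1 adjusted over the list alone), with Insig1 (-2.18 ± 0.26), Stard4 (-1.48 ± 0.28) and Hmgcs1 (-1.11 ± 0.21) ahead. Tested as a list, it had a camera adjusted p of 0.00491, and adjusted p = 0.794 with an estimated correlation. Of 30 fatty acid and triglyceride synthesis genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), with Acly (-2.27 ± 0.32), Gpam (-1.66 ± 0.29) and Scd1 (-1.78 ± 0.35). Camera gave this list an adjusted p of 0.0276, and adjusted p = 0.802 with an estimated correlation. Of 34 amino acid catabolism genes 11 fell and 0 rose (11 and 0 adjusted over the list alone), with Tdo2 (-1.66 ± 0.31, and -1.04 without control 1), Oat (-1.74 ± 0.37) and Hgd (-0.87 ± 0.19), at a camera adjusted p of 0.0274, and adjusted p = 0.802 with an estimated correlation.

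Kupffer cell markers and thyroid hormone responsive genes were higher. Of 24 macrophage genes 8 rose and 1 fell (the same numbers adjusted over the list alone), with the Kupffer cell genes Clec4f (1.41 ± 0.15), Cd5l (1.21 ± 0.21) and Cd163 (1.85 ± 0.33) ahead, and 11 rose without control 2 and glucagon 3 (camera adjusted p = 0.000157, and adjusted p = 0.794 with an estimated correlation). Of 24 thyroid hormone responsive genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00409, and adjusted p = 0.794 with an estimated correlation). Dio1, the deiodinase that converts thyroid hormones, went from 105 ± 48.6 to 449 ± 81.1 CPM (2.10 ± 0.31), and Idh3a (1.46 ± 0.16) and Bcl3 (2.48 ± 0.37) rose. Of 25 cell cycle genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), Rrm2 (1.51 ± 0.39) and Ccne1 (1.19 ± 0.32), with Mcm3 next (0.89 ± 0.33, edgeR adjusted p = 0.0626, and 0.0116 without control 2), and 14 rose without control 2 and glucagon 3. The camera adjusted p was 0.000514, and adjusted p = 0.795 with an estimated correlation.

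Of 30 acute phase genes 3 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.0203, and adjusted p = 0.802 with an estimated correlation), and their calls ended when any 1 of several libraries was left out. The metallothionein Mt1 (2.77 ± 0.78) was not called without T3 4 (edgeR adjusted p = 0.165) or control 1 (0.0557), Mt2 (2.89 ± 0.83) without T3 4 (0.185) or control 1 (0.0516), and Serpina3n (0.87 ± 0.29) without T3 4 (0.203), control 1 (0.123), control 2 (0.0668), control 3 (0.0834) or T3 1 (0.0827). Of 20 periportal hepatocyte genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), with Agxt2l1 (-4.39 ± 0.45), Hsd17b6 (-4.48 ± 0.70) and Hsd17b13 (-1.40 ± 0.24). That call (camera adjusted p = 0.0377, and adjusted p = 0.794 with an estimated correlation) ended without control 2 and glucagon 3 (0.0602). Of 24 unfolded protein and integrated stress genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), with Herpud1 (-1.09 ± 0.18), Manf (-1.23 ± 0.23) and Dnajb9 (-1.5 ± 0.28), and that call (camera adjusted p = 0.0461, and adjusted p = 0.802 with an estimated correlation) ended without these 2 libraries too (0.405, with 5 genes lower and 3 higher).

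The highest changes of ranked genes after T3 were in Sspo (5.41 ± 0.52), Cyp3a16 (5.29 ± 1.00), Ttbk1, a tau kinase (4.71 ± 0.37), Ces4a (4.59 ± 0.89), Ugt2b37 (4.50 ± 0.45) and the chemokine Cxcl14 (4.38 ± 0.85). Besides Cyp4a12a, Hsd17b6 and Agxt2l1, the lowest ranked genes were Serpina7, which encodes thyroxine-binding globulin (-4.27 ± 0.45), the succinate receptor Sucnr1 (-3.94 ± 0.56) and Ddah1 (-3.67 ± 0.63). Of the genes set in advance, Gcgr (0.31 ± 0.22), Thrb (-0.47 ± 0.19), Thrsp (-0.22 ± 0.56), Pck1 (0.00 ± 0.27), Cyp7a1 (1.2 ± 0.43, edgeR adjusted p = 0.0591) and Fgf21 (2.00 ± 0.72, edgeR adjusted p = 0.0577) were not called, and Fgf21 was called without control 2 (4.16, edgeR adjusted p = 4.09e-05) and with the replicate number as a block (0.0216). Thrb was called without control 2 (-0.60, edgeR adjusted p = 0.0273), and Cyp7a1 without T3 1 (1.43, edgeR adjusted p = 0.042) and with DESeq2 (0.0247).

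edgeR called 2317 genes between T3 and control, 944 higher and 1373 lower. A fit of these groups alone called 503, and leaving out 1 library at a time gave 1528 (without T3 1) to 3179. Lane and treatment cannot be separated for single genes here. Of the 2317 genes, 2087 (90.1%) had the same direction in combination against glucagon, which lies within lanes 1 to 4 and shares no library with this comparison. That argues against the lane as the source of the whole pattern.

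T3 on a glucagon background, combination against glucagon, was the effect of T3 between groups that share lanes, and the cAMP-CREB early target genes were lower when T3 was added. Of 19 genes 15 fell and 1 rose (16 and 1 adjusted over the list alone), with Ppargc1a at 178 ± 20.6 CPM after glucagon and 14.1 ± 2.46 after combination (-3.65 ± 0.20), Nr4a2 changed by -4.15 ± 0.25 and Nr4a3 by -4.97 ± 0.35. This list had a camera adjusted p of 3.91e-12, and adjusted p = 0.0162 with an estimated correlation. Glucose production and amino acid genes were lower too: 7 of 19 gluconeogenesis genes fell and 0 rose (8 and 0 adjusted over the list alone), with Pck1 at 1200 ± 358 CPM (-2.26 ± 0.29) and G6pc (-1.59 ± 0.23) beside Ppargc1a. For that list camera gave an adjusted p of 0.000381, and adjusted p = 0.116 with an estimated correlation. Of 34 amino acid catabolism genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), with Slc38a2 (-2.79 ± 0.20), Tat, tyrosine aminotransferase (-2.8 ± 0.22), and Slc7a2 (-1.52 ± 0.19). Tested with camera, these had an adjusted p of 0.00107, and adjusted p = 0.598 with an estimated correlation. Of 24 unfolded protein and integrated stress genes 11 fell and 0 rose (13 and 0 adjusted over the list alone), among them Herpud1 (-1.56 ± 0.18), Chac1 (-2.04 ± 0.31) and Ddit4 (-1.94 ± 0.34), at a camera adjusted p of 0.00107, and adjusted p = 0.573 with an estimated correlation.

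Both sex-biased lists were called in the same directions as after T3 alone, though not every member moved with its list. In the male-biased list 9 of 20 fell and 1 rose (11 and 1 adjusted over the list alone), with Elovl3, a fatty acid elongase (-4.26 ± 0.38), Cyp4a12a (-7.47 ± 0.72) and Keg1 (-2.79 ± 0.33). The camera adjusted p was 2.44e-06, and adjusted p = 0.573 with an estimated correlation. In the female-biased list 9 of 14 rose and 1 fell (10 and 1 adjusted over the list alone), with Cyp17a1 (3.87 ± 0.36), Cyp3a44 (6.80 ± 0.94) and Cyp3a16 (7.91 ± 1.16). Camera gave this list an adjusted p of 0.000176, and adjusted p = 0.573 with an estimated correlation. Of 35 drug metabolism genes 14 fell and 3 rose (16 and 3 adjusted over the list alone), with Ephx1 (-1.65 ± 0.19), Gstp1 (-2.98 ± 0.40) and Ces2a (-1.99 ± 0.31), at a camera adjusted p of 0.00182, and adjusted p = 0.573 with an estimated correlation. Of 24 macrophage genes 15 rose and 0 fell (18 and 0 adjusted over the list alone), with Clec4f (1.48 ± 0.15), Cd5l (1.51 ± 0.21) and the complement gene C1qa (1.18 ± 0.17). That list's camera adjusted p was 2.83e-08, and adjusted p = 0.445 with an estimated correlation. Of 25 cell cycle genes 14 rose and 0 fell (15 and 0 adjusted over the list alone), with Mki67, a marker of dividing cells (2.98 ± 0.50), Birc5 (2.52 ± 0.46) and Foxm1 (2.39 ± 0.49). Its camera adjusted p was 6.44e-06, and adjusted p = 0.573 with an estimated correlation.

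Among ranked genes Cux2 (5.21 ± 1.03), Arrdc3 (4.41 ± 0.33), Ugt2b37 (4.31 ± 0.46) and Cyp7a1, from 20.1 ± 19.3 to 382 ± 123 CPM (4.26 ± 0.49), rose most besides Cyp3a16 and Cyp3a44. Tas1r2 (-5.23 ± 0.40), BC057022 (-4.76 ± 0.39), Btbd19 (-4.73 ± 0.25), Hsd17b6 (-4.63 ± 0.69) and Klf4 (-4.42 ± 0.36) fell most besides Nr4a3, while Cyp4a12a, given above, fell further and is not ranked. Dio1 rose by 1.85 ± 0.31, while Thrb, the T3 receptor of the liver, fell (-1.02 ± 0.19), and Gcgr (0.23 ± 0.22), Thrsp (0.69 ± 0.56) and Fgf21 (1.24 ± 0.70) were not called.

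edgeR called 2906 genes between combination and glucagon, 1595 higher and 1311 lower. Across genes, the T3 effect against control and this effect, which share no libraries, correlated with r = 0.583 (genes are not independent replicates). Of the genes called after T3 alone, 542 were higher in both and 471 lower in both, against 116.7 and 139.5 for independent lists, and 48 went opposite ways.

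**Figure D2:**
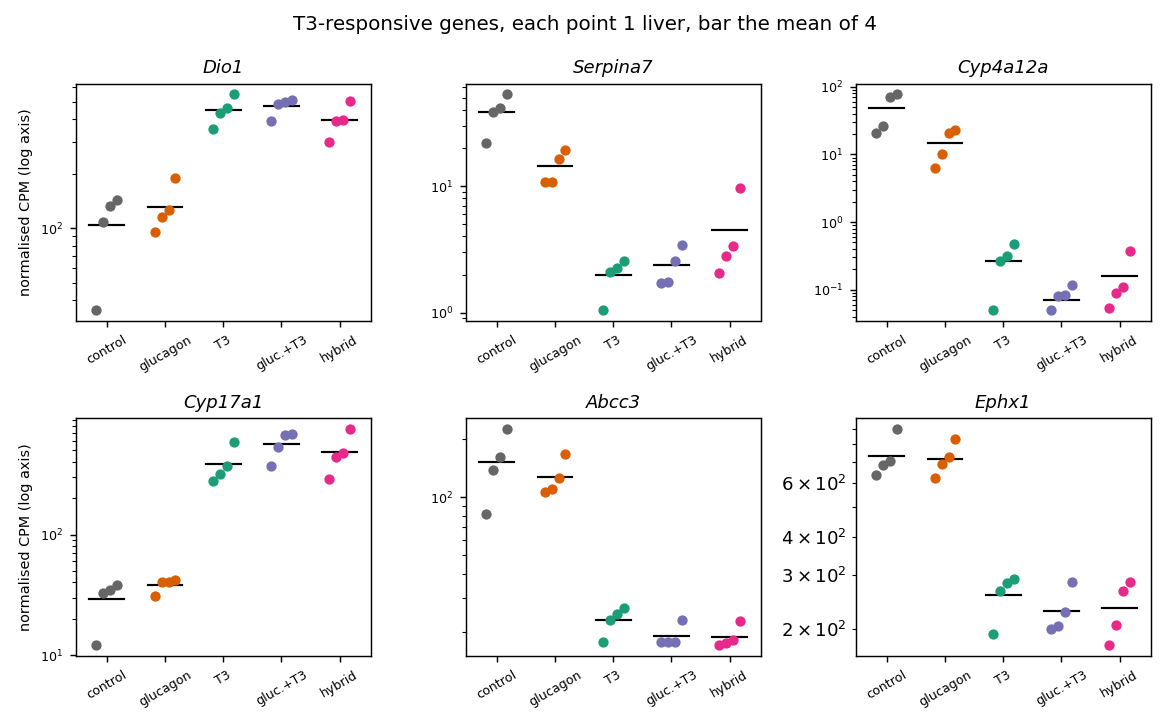
Normalised CPM (log axis) of 6 genes that respond to T3 in the 5 treatment groups, each point 1 liver and each bar the mean of 4, with points under 0.05 CPM drawn at 0.05. Dio1 averaged 449, 473 and 399 CPM in the T3, combination and hybrid groups and 105 and 131 CPM in control and glucagon.

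The combination was set against control to ask what both hormones do together, and the male-biased list had the smallest p. In the male-biased list 11 of 20 genes fell and 1 rose (12 and 1 adjusted over the list alone), led by Cyp4a12a at 0.0701 ± 0.05 CPM (-9.16 ± 0.72), Cyp4a12b (-8.10 ± 0.87) and Keg1 (-3.68 ± 0.34). The mean of Cyp4a12a lies under the level of 3 counts in these libraries (0.20 to 0.30 CPM), so the size of its changes in the combination is uncertain. For that list camera gave an adjusted p of 6.63e-07, and adjusted p = 0.652 with an estimated correlation. In the female-biased list 7 of 14 rose and 1 fell (8 and 2 adjusted over the list alone), with Cyp17a1 (4.26 ± 0.36), Cyp39a1 (2.35 ± 0.30) and Cyp3a44 (5.47 ± 0.84). Tested with camera, these had an adjusted p of 1.6e-05, and adjusted p = 0.652 with an estimated correlation. Of 35 drug metabolism genes 17 fell and 2 rose (19 and 3 adjusted over the list alone), with Ephx1 (-1.68 ± 0.19) and Cyp3a11 (-2.54 ± 0.38) lower and Sult1a1 higher (1.60 ± 0.22). Camera gave this list an adjusted p of 0.000652, and adjusted p = 0.652 with an estimated correlation. Of 25 bile acid genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with Abcc3 (-3.00 ± 0.24), Scp2 (-1.58 ± 0.24) and Acox2 (-1.08 ± 0.21). For that list camera gave an adjusted p of 0.00471, and adjusted p = 0.995 with an estimated correlation. Of 24 thyroid hormone responsive genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with Idh3a (2.25 ± 0.16), Slc16a10 (1.58 ± 0.17) and Dio1 (2.18 ± 0.31) ahead, at a camera adjusted p of 0.000652, and adjusted p = 0.374 with an estimated correlation.

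Of 25 cell cycle genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), Rrm2 (2.17 ± 0.38) and Ccne1 (1.26 ± 0.31), with Aurkb next (1.28 ± 0.52, edgeR adjusted p = 0.0849), and 13 rose without control 2 and glucagon 3 (camera adjusted p = 0.00779, and adjusted p = 0.995 with an estimated correlation). The other ranked genes with the highest changes were Cux2 (6.59 ± 1.15), Cyp3a16 (6.08 ± 1.03), Ugt2b37 (4.25 ± 0.45) and Ces4a (3.98 ± 0.87). Besides Cyp4a12a, the lowest ranked genes were Sucnr1 (-4.15 ± 0.56), Serpina7 (-4.03 ± 0.43), Cyp2c44 (-3.99 ± 0.39), Hsd17b6 (-3.97 ± 0.67) and Mup20 (-3.94 ± 0.77). Cyp7a1 rose by 2.00 ± 0.44 and Thrb fell by 1.02 on the log2 scale (SE 0.19). Pck1 (-0.49 ± 0.27), Gcgr (-0.08 ± 0.22), Thrsp (0.24 ± 0.56) and Fgf21 (1.43 ± 0.71) were not called, and Fgf21 was called without control 2 (3.59, edgeR adjusted p = 9.28e-05).

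edgeR called 2598 genes between combination and control, 1191 higher and 1407 lower. A fit of these groups alone called 918, and leaving out 1 library at a time gave 1855 to 3552.

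The hybrid was set against control to ask what the single molecule does, and the cell cycle list had the smallest p. Of its 25 genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with Rrm2 (2.75 ± 0.39), Ccne1 (1.87 ± 0.31) and the mitotic kinase Aurkb (2.29 ± 0.52), and 20 rose without control 2 and glucagon 3 (camera adjusted p = 3.29e-07, and adjusted p = 0.511 with an estimated correlation). Of 20 male-biased genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), led by Cyp4a12a (-8.36 ± 0.66), Keg1 (-4.47 ± 0.36) and Elovl3 (-3.31 ± 0.36). That list's camera adjusted p was 5.23e-07, and adjusted p = 0.511 with an estimated correlation. Of 14 female-biased genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Cyp17a1 (4.05 ± 0.36), Cyp39a1 (2.43 ± 0.30) and Cyp3a44 (5.35 ± 0.83). The camera adjusted p was 0.00012, and adjusted p = 0.511 with an estimated correlation.

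Drug metabolism genes fell: 21 of 35 were lower and 3 higher (25 and 4 adjusted over the list alone), with Ephx1 (-1.65 ± 0.19), Aox3 (-2.56 ± 0.30) and Cyp3a11 (-2.61 ± 0.38). Camera gave this list an adjusted p of 5.23e-07, and adjusted p = 0.511 with an estimated correlation. Of 25 bile acid genes 16 fell and 0 rose (18 and 1 adjusted over the list alone), with Abcc3 (-3.00 ± 0.24), Scp2 (-1.71 ± 0.24) and Acox2 (-1.44 ± 0.21). For that list camera gave an adjusted p of 1.57e-06, and adjusted p = 0.511 with an estimated correlation. Of 24 macrophage genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with Clec4f (1.24 ± 0.15), Timd4 (1.42 ± 0.28) and Cd163 (1.67 ± 0.33), and 9 rose without control 2 and glucagon 3 (camera adjusted p = 0.00712, and adjusted p = 0.844 with an estimated correlation). Of 24 thyroid hormone responsive genes 9 rose and 1 fell (10 and 3 adjusted over the list alone), with Idh3a (2.45 ± 0.16), Slc16a10 (1.53 ± 0.17) and Hr (3.64 ± 0.51). That call (camera adjusted p = 0.0211, and adjusted p = 0.511 with an estimated correlation) ended without control 2 and glucagon 3 (0.128).

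The highest changes of ranked genes were in Cyp3a16 (5.85 ± 1.02), the phosphate transporter Slc34a2 (5.65 ± 0.65), Akr1b7 (5.54 ± 0.72), Cyp3a44, Ces4a (4.61 ± 0.89) and Mt1 (4.16 ± 0.83). The lowest of them, besides Cyp4a12a and Keg1, were in Rgs16 (-5.54 ± 0.88), Inmt (-5.26 ± 0.56), Sucnr1 (-4.43 ± 0.56) and the carbonic anhydrase Car3 (-4.14 ± 0.54). Dio1 rose by 1.93 ± 0.31 and Thrb fell by 1.14 on the log2 scale (SE 0.19). Gcgr, the glucagon receptor, changed by -0.70 ± 0.23 (edgeR adjusted p = 0.0275), a call that ended without control 1 (0.0553), control 3 (0.0782), control 4 (0.0521), hybrid 2 (0.102) or hybrid 3 (0.0565). Pck1 (0.32 ± 0.27), Cyp7a1 (1.06 ± 0.43), Thrsp (-0.58 ± 0.56) and Fgf21 (0.94 ± 0.70) were not called, and Fgf21 was called without control 2 (3.11, edgeR adjusted p = 0.000234).

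edgeR called 3144 genes between hybrid and control, 1440 higher and 1704 lower. A fit of these groups alone called 1208, and leaving out 1 library at a time gave 2333 to 3719. Of these calls 940 were higher and 1074 lower in combination too, against 132.9 and 185.8 for independent lists, and 0 went opposite ways, but these lists share their controls. Simulated unchanged groups shared 1.97 calls on average. Across genes the hybrid and combination effects correlated with r = 0.894, where simulated unchanged groups against these controls gave 0.794 on average. With the controls split into pairs, so that the effects share none, r was 0.508 on average (0.405 to 0.611), and 499 genes were higher and 490.8 lower in both on average (109.7 and 145.7 for independent lists), with 30.2 opposite. The covariance was 0.555 against 0.157 simulated, a difference of 0.398. For hybrid with T3 r was 0.739 (0.773 simulated, 0.375 with split controls), with a covariance of 0.452 against 0.157, 589 genes higher and 787 lower in both (105.3 and 181.3 for independent lists) and 8 opposite. Split controls gave 296.8, 342.5 and 61.5 of these (86.6 and 124.3 for independent lists), and simulated groups shared 2.25 calls. For hybrid with glucagon r was 0.398 (0.751 simulated, 0.137 with split controls), with a covariance of 0.264 against 0.156, 511 genes higher and 517 lower in both (132.9 and 203.4 for independent lists) and 93 opposite. Split controls gave 314.3, 254 and 201.5 of these (114.9 and 164.5 for independent lists), and simulated groups shared 3.19 calls.

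The hybrid was set against the combination to ask whether joining the hormones differs from giving both, and few single genes differed. Arrdc3 was lower after the hybrid, at 19.6 ± 5.25 against 113 ± 22.1 CPM (-2.53 ± 0.30, edgeR adjusted p = 0.000765). Also called, and named after their values were seen, were Gprin3 (-1.64, edgeR adjusted p = 0.0098) and 8430408G22Rik (-3.18, edgeR adjusted p = 0.00646). The call of Gprin3 ended without combination 1 (0.0527), hybrid 2 (0.059), hybrid 3 (0.0622) or hybrid 4 (0.0632), and that of 8430408G22Rik without hybrid 3 (0.0622) or hybrid 4 (0.0531). edgeR called 4 genes in all, 0 higher and 4 lower, with 891 at an unadjusted p under 0.05, while DESeq2 called 28 and an edgeR fit of these groups alone 16. Without hybrid 2 edgeR called 2, and 1 each without hybrid 3 and without hybrid 4.

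As lists, 9 of the 28 differed between the molecules by camera at its preset correlation, but 0 did with an estimated correlation and 0 by fry, which tests a list without comparing it with other genes. The cell cycle list was higher after the hybrid (camera adjusted p = 2.96e-09, and adjusted p = 0.629 with an estimated correlation), though 0 of 25 members were called, with Birc5 at 1.04 ± 0.40, Aurka at 1.18 ± 0.49 and Cdk1 at 0.94 ± 0.41. The bile acid list (3.68e-05) and the drug metabolism list (8.2e-05) were lower, both with adjusted p = 0.629 with an estimated correlation and 0 members called. Their first members were Cyp8b1 (-1.18 ± 0.39), Abcc2 (-0.42 ± 0.16) and Cyp7a1 (-0.94 ± 0.43), and Aox3 (-0.85 ± 0.29), Sult1a1 (-0.60 ± 0.22) and Ces1g (-1.13 ± 0.47). Fatty acid oxidation (0.0089), with Acaa1b (-0.83 ± 0.31) and Etfb (-0.39 ± 0.15), and pericentral genes (0.0114), with Gulo (-0.43 ± 0.18), Cyp7a1 and Aldh3a2 (-0.42 ± 0.19), were lower as lists, both with adjusted p = 0.783 with an estimated correlation. So were lipoprotein genes (0.0124, and adjusted p = 0.629 with an estimated correlation), with Apoc3 (-0.46 ± 0.18), Apoc1 (-0.55 ± 0.26) and Apoe (-0.42 ± 0.22), and fatty acid and triglyceride synthesis (0.0146, and adjusted p = 0.783 with an estimated correlation), with Mlxipl at -0.91 ± 0.34 and G6pdx at 0.76 ± 0.32. Macrophage genes (0.0146), with Cd9 (0.66 ± 0.27), Ccr2 (1.14 ± 0.57) and Ctss (0.59 ± 0.36), and sinusoidal endothelial genes (0.0425), with Kdr (0.37 ± 0.18), Lyve1 (0.54 ± 0.31) and Dpp4 (-0.29 ± 0.19), were higher as lists, both with adjusted p = 0.783 with an estimated correlation. In all 9 lists the counts adjusted over the list alone equalled those over all genes. With the lane as a block the cAMP-CREB list was called as well (camera adjusted p = 0.0407).

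For the genes set in advance, the 95% intervals of the log2 difference, hybrid minus combination, were -1.10 to -0.16 for Gcgr, -0.51 to 0.28 for Thrb, -0.87 to 0.38 for Dio1, 0.24 to 1.39 for Pck1, -1.84 to -0.04 for Cyp7a1 and -1.93 to 0.95 for Fgf21. None of these was called after adjustment over all genes, nor was Thrsp (-0.83 ± 0.56). Doses are not given in the sources used here, so equal doses of the molecules cannot be assumed.

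The hybrid was set against glucagon, one of its parts, and its cell cycle and macrophage genes were higher. Of 25 cell cycle genes 20 rose and 0 fell (22 and 0 adjusted over the list alone), with Birc5 (3.57 ± 0.46), Mki67 from 2.34 ± 0.707 to 35.5 ± 13.2 CPM (3.89 ± 0.52) and Foxm1 (3.35 ± 0.50). For that list camera gave an adjusted p of 6.58e-11, and adjusted p = 0.306 with an estimated correlation. Of 24 macrophage genes 19 rose and 0 fell (21 and 0 adjusted over the list alone), with Clec4f (1.62 ± 0.15), Cd5l (1.78 ± 0.21) and Csf1r (1.19 ± 0.18). Tested with camera, these had an adjusted p of 6.58e-11, and adjusted p = 0.235 with an estimated correlation. The cAMP-CREB list fell, with 13 of 19 lower and 0 higher (15 and 0 adjusted over the list alone): Ppargc1a changed by -3.12 ± 0.19, Nr4a2 by -3.94 ± 0.25 and Nr4a3 by -5.17 ± 0.35 (camera adjusted p = 6.62e-11, and adjusted p = 0.0308 with an estimated correlation). Of 20 male-biased genes 10 fell and 1 rose (14 and 1 adjusted over the list alone), with Elovl3 (-4.70 ± 0.39), Keg1 (-3.58 ± 0.34) and Cyp4a12a (-6.67 ± 0.66). Tested with camera, these had an adjusted p of 1.25e-06, and adjusted p = 0.394 with an estimated correlation. Of 14 female-biased genes 9 rose and 0 fell (9 and 2 adjusted over the list alone), with Cyp17a1 (3.66 ± 0.35), Cyp3a44 (6.68 ± 0.93) and Cyp3a16 (7.69 ± 1.16). That list's camera adjusted p was 0.0005, and adjusted p = 0.394 with an estimated correlation.

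Further lists were lower than after glucagon. Of 35 drug metabolism genes 17 fell and 1 rose (20 and 2 adjusted over the list alone), with Ephx1 (-1.62 ± 0.19), Ces2a (-2.62 ± 0.32) and Gstp1 (-2.74 ± 0.39), at a camera adjusted p of 1.46e-06, and adjusted p = 0.235 with an estimated correlation. Of 19 gluconeogenesis genes 11 fell and 0 rose (11 and 0 adjusted over the list alone), with Ppargc1a and Pck1 (-1.45 ± 0.28). Tested with camera, these had an adjusted p of 8.73e-05, and adjusted p = 0.0676 with an estimated correlation. Of 34 amino acid catabolism genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with Slc38a2 (-2.30 ± 0.20), Tat (-2.02 ± 0.22) and Slc7a2 (-1.29 ± 0.19). That list's camera adjusted p was 0.000127, and adjusted p = 0.394 with an estimated correlation. In the circadian clock list 8 of 18 fell and 2 rose (8 and 4 adjusted over the list alone), with Nfil3 (-2.53 ± 0.26), Per2 (-2.47 ± 0.27) and Cry2 (-1.82 ± 0.21), at a camera adjusted p of 0.00939, and adjusted p = 0.394 with an estimated correlation. The remaining called lists were also lower: unfolded protein and integrated stress (0.0012), lipoprotein (0.00826), fatty acid and triglyceride synthesis (0.00914), bile acid (0.00939) and mitochondrial respiratory chain (0.0387), with adjusted p = 0.394, 0.383, 0.569, 0.569 and 0.569 with an estimated correlation. Among their members were Herpud1 (-1.93 ± 0.18), Chac1 (-2.26 ± 0.31) and Ddit4 (-1.83 ± 0.33), then Abca1 (-1 ± 0.19) and Apoc1 (-1.35 ± 0.26), then Acsl3 (-1.96 ± 0.22), Lpin1 (-2.09 ± 0.28) and Srebf1 (-2.46 ± 0.37), then Abcc3 (-2.75 ± 0.24), Cyp7a1, which was higher (3.33 ± 0.47), and Scp2 (-1.67 ± 0.24). Counts of lower and higher members in these lists were 10 and 1 of 24, 9 and 2 of 29, 11 and 4 of 30, 9 and 3 of 25 and 2 and 0 of 36, and adjusted over the list alone they were 11 and 1, 11 and 2, 11 and 4, 13 and 3 and 0 and 0. The respiratory chain calls ended when any 1 of several libraries was left out. Sdha (-0.51 ± 0.17) was not called without glucagon 1 (edgeR adjusted p = 0.098), hybrid 2 (0.102) or hybrid 4 (0.0747). Sdhc (-0.49 ± 0.16) was not called without glucagon 1 (0.069), glucagon 2 (0.0516), glucagon 3 (0.0718), hybrid 2 (0.0873), hybrid 3 (0.0732) or hybrid 4 (0.0526), while Uqcrfs1 stood at -0.35 ± 0.15.

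Besides Cyp3a16, Cyp3a44 and Cyp17a1, the highest changes of ranked genes were in Lcn2, lipocalin 2 (4.92 ± 1.17), Cxcl14 (4.21 ± 0.85) and Cyp4a31 (4.12 ± 0.48). The lowest of them, besides Nr4a3 and Elovl3, were in Inmt (-5.50 ± 0.57), Tas1r2 (-5.44 ± 0.40), Car3 (-4.89 ± 0.56) and Btbd19 (-4.75 ± 0.25). Dio1 rose by 1.60 ± 0.31 and Thrb fell by 1.14 on the log2 scale (SE 0.19), and Gcgr (-0.39 ± 0.22), Thrsp (-0.13 ± 0.56) and Fgf21 (0.75 ± 0.70) were not called. edgeR called 3255 genes between hybrid and glucagon, 1751 higher and 1504 lower.

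The hybrid was set against T3, its other part, and amino acid genes were higher. Of 34 amino acid catabolism genes 11 rose and 0 fell (18 and 2 adjusted over the list alone), with Slc25a15, the mitochondrial ornithine carrier, from 134 ± 26.6 to 463 ± 64.5 CPM (1.79 ± 0.18), Got1 (2.41 ± 0.29) and Agxt (2.15 ± 0.29), at a camera adjusted p of 1.03e-06, and adjusted p = 0.746 with an estimated correlation. Of 19 cAMP-CREB genes 5 rose and 0 fell (5 and 1 adjusted over the list alone), with the kinase Sik1 (2.65 ± 0.31), Ppargc1a (1.5 ± 0.19) and Nr4a2 (2.25 ± 0.30), at a camera adjusted p of 0.00503. Of 20 periportal genes 2 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0241), Agxt2l1 (4.48 ± 0.45) and Asl, a urea cycle enzyme (0.77 ± 0.18, not called without T3 1, 0.0543, or hybrid 1, 0.0501), while Sds stood at 0.94 ± 0.29. The cell cycle list was higher (camera adjusted p = 0.00522), with 1 of 25 called (0 adjusted over the list alone), Rrm2 (1.24 ± 0.37), and with Foxm1 at 1.29 ± 0.46 and Aurkb at 1.41 ± 0.51. Each of these lists after the first also had adjusted p = 0.746 with an estimated correlation.

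Drug metabolism, bile acid and male-biased lists were lower, each at a camera adjusted p of 0.00781, and adjusted p = 0.746 with an estimated correlation. Called members were Aox3 (-1.61 ± 0.29), Cyp2a5 (-1.72 ± 0.48) and Cyp2e1 (-1.27 ± 0.38) of 35, Hsd3b7 (-0.78 ± 0.22) of 25, with Acox2 at -0.59 ± 0.21 and Cyp8b1 at -1.10 ± 0.39, and Elovl3 (-1.86 ± 0.35) and Keg1 (-1.37 ± 0.32) of 20, with Mup21 at -1.91 ± 0.68. Adjusted over the list alone 3, 1 and 6 members fell and 0 rose. Several calls ended with 1 library left out. Rrm2 was not called without T3 1 (0.158), T3 2 (0.115), T3 4 (0.0922), hybrid 2 (0.129), hybrid 3 (0.134) or hybrid 4 (0.0609), and Cyp2a5 not without T3 1 (0.136), T3 2 (0.0853), hybrid 1 (0.0575), hybrid 2 (0.119) or hybrid 4 (0.096). Cyp2e1 was not called without any 1 of the 8 libraries (0.0523 to 0.133), Hsd3b7 not without T3 1 (0.1), T3 2 (0.108), T3 4 (0.0828) or any hybrid library (0.0583 to 0.131), and Keg1 not without T3 2 (0.0501), hybrid 1 (0.0504) or hybrid 2 (0.0609). With the replicate number as a block, which marks no lane for T3, Rrm2 (0.0692) and Cyp2e1 (0.0514) were not called.

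The highest changes of ranked genes besides Agxt2l1 and Sik1 were in Pde10a (3.16 ± 0.57), the leptin receptor Lepr (2.94 ± 0.32), Pmvk (2.90 ± 0.34) and Cdc42ep5 (2.78 ± 0.52). The lowest of them were in Rgs16 (-3.96 ± 0.83), B3galt1 (-2.87 ± 0.53), Egr1 (-2.60 ± 0.74), the clock output gene Dbp (-2.15 ± 0.35), Arhgef10l (-2.04 ± 0.25) and Car3 (-1.95 ± 0.49). Egr1 was not called without T3 1 (0.156), T3 2 (0.0805) or any hybrid library (0.0812 to 0.0938), nor Car3 without T3 2 (0.102), hybrid 1 (0.0649) or hybrid 2 (0.084). Gcgr fell by 1.02 on the log2 scale (SE 0.23) and Thrb by 0.67 (SE 0.19), the latter not called without any 1 of the 8 libraries (0.0565 to 0.113). Dio1 (-0.17 ± 0.30), Pck1 (0.32 ± 0.27), Cyp7a1 (-0.14 ± 0.43), Thrsp (-0.37 ± 0.56) and Fgf21 (-1.06 ± 0.70) were not called. edgeR called 821 genes, 476 higher and 345 lower, and a fit of these groups alone 1562. Without hybrid 2 it called 406, without T3 1 415, without hybrid 3 468, without T3 2 476 and without T3 4 541. Lane 5 held all T3 libraries here too.

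Whether the combination departed from the sum of the single effects was tested as an interaction on the log scale, and the cAMP-CREB genes fell below that sum. Of 19 genes 9 were lower and 1 higher than the sum (12 and 1 adjusted over the list alone), with Ppargc1a at -3.07 ± 0.27, Nr4a2 at -3.74 ± 0.42 and Pde4d, a cAMP phosphodiesterase, at -2.26 ± 0.30 (camera adjusted p = 5.17e-15, and adjusted p = 0.00611 with an estimated correlation). Of 19 gluconeogenesis genes 3 were lower and 0 higher (6 and 0 adjusted over the list alone), Ppargc1a, Pck1 (-2.26 ± 0.39) and Got1 (-1.44 ± 0.39), at a camera adjusted p of 0.00385, and adjusted p = 0.186 with an estimated correlation. Of 18 clock genes 5 were lower and 0 higher (5 and 3 adjusted over the list alone), among them Per2 (-2.83 ± 0.37), Cry2 (-1.85 ± 0.29) and Per1 (-2.43 ± 0.45), and of 24 thyroid hormone responsive genes 2 were lower and 1 higher (2 and 1 adjusted over the list alone): Ppargc1a, Bcl3 (-1.97 ± 0.50) and, above the sum, Cyp7a1 (3.06 ± 0.62). These calls (camera adjusted p = 0.0364 and 0.0241, and adjusted p = 0.897 and adjusted p = 0.497 with an estimated correlation) ended without control 2 and glucagon 3 (0.276 and 0.0943). Of 30 acute phase genes 2 were lower and 0 higher (3 and 0 adjusted over the list alone), Mt2 (-4.93 ± 1.15) and Socs3 (-1.97 ± 0.49), with Mt1 at -3.81 ± 1.07 (called without control 2, 0.014, or T3 2, 0.0197). The camera adjusted p was 0.0228, and adjusted p = 0.897 with an estimated correlation. Of 25 bile acid genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone), Cyp7a1 and Nr1h4 (1.68 ± 0.41), with Abcb4 at 0.62 ± 0.22. Camera gave this list an adjusted p of 0.0364, and adjusted p = 0.897 with an estimated correlation.

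Above the sum the largest departures of ranked genes besides Cyp7a1 were in Rgs16 (5.43 ± 1.08), Arrdc3 (5.40 ± 0.44), the pseudogene Cyp2d37-ps (2.90 ± 0.59), Rnf144b (2.88 ± 0.28) and Fam13a (2.86 ± 0.61). Below it, besides Mt2, they were in BC057022 (-5.94 ± 0.53), Nr4a3 (-5.41 ± 0.75), Tas1r2 (-5.39 ± 1.26), Akr1b7 (-4.91 ± 0.91) and Btbd19 (-4.38 ± 0.33). Calls that ended with 1 library left out were Tas1r2 without T3 2 (0.0741) or T3 3 (0.0675), Mt2 without T3 4 (0.06), Bcl3 without T3 2 (0.0528), T3 4 (0.0558) or combination 4 (0.0506), and Nr1h4 without glucagon 2 (0.0582), T3 1 (0.0538) or combination 3 (0.0572), and without control 1 Nr1h4 stood at 1.11. Socs3 was not called without glucagon 1 (0.0577), glucagon 2 (0.0672), T3 1 (0.0573), T3 4 (0.0726), combination 2 (0.0556) or combination 4 (0.0595), or with the replicate number as a block (0.0547). Got1 was not called without any 1 of 12 libraries (0.0509 to 0.102), that is each except control 2, control 4, T3 3 and combination 2, nor without control 2 and glucagon 3 together (0.0535). Gcgr (-0.08 ± 0.32), Thrb (-0.55 ± 0.27), Dio1 (-0.26 ± 0.43), Thrsp (0.91 ± 0.79) and Fgf21 (-0.75 ± 0.98) were not called, though Fgf21 was without control 2 (-2.93, edgeR adjusted p = 0.0105). edgeR called 482 genes, 206 above and 276 below the sum, and 821 without control 3. The T3 group, all in lane 5, enters this test.

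In these comparisons 7 of the 28 lists were never called by camera with all libraries, with lowest adjusted p values of 0.0633 for the tricarboxylic acid cycle, 0.12 for hepatokines and growth factors, 0.168 for hormone receptors and T3 handling, 0.065 for lymphocytes and granulocytes, 0.146 for stellate cells and fibroblasts, 0.146 for cholangiocytes and 0.2 for blood, fat and pancreas. Without control 2 and glucagon 3 the lymphocyte and granulocyte list was called higher in T3 against control (camera adjusted p = 0.00531), hybrid against glucagon (0.00373) and combination against glucagon (0.0246). These calls used the preset correlation, and an estimated one was not tried without these libraries.

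The genes set in advance lie on GRCm38 as follows, and all are annotated as protein coding (GENCODE M21). Gcgr lies on chromosome 11 from 120530699 to 120538986 on the plus strand and Thrb on chromosome 14 from 17660261 to 18038090 (plus). Pck1 lies on chromosome 2 from 173153048 to 173159273 (plus). On the minus strand lie Dio1 on chromosome 4 from 107291465 to 107307169, Cyp7a1 on the same chromosome from 6265612 to 6275633, Thrsp on chromosome 7 from 97412938 to 97417730 and Fgf21 on chromosome 7 from 45613886 to 45615490.

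**Figure D3:**
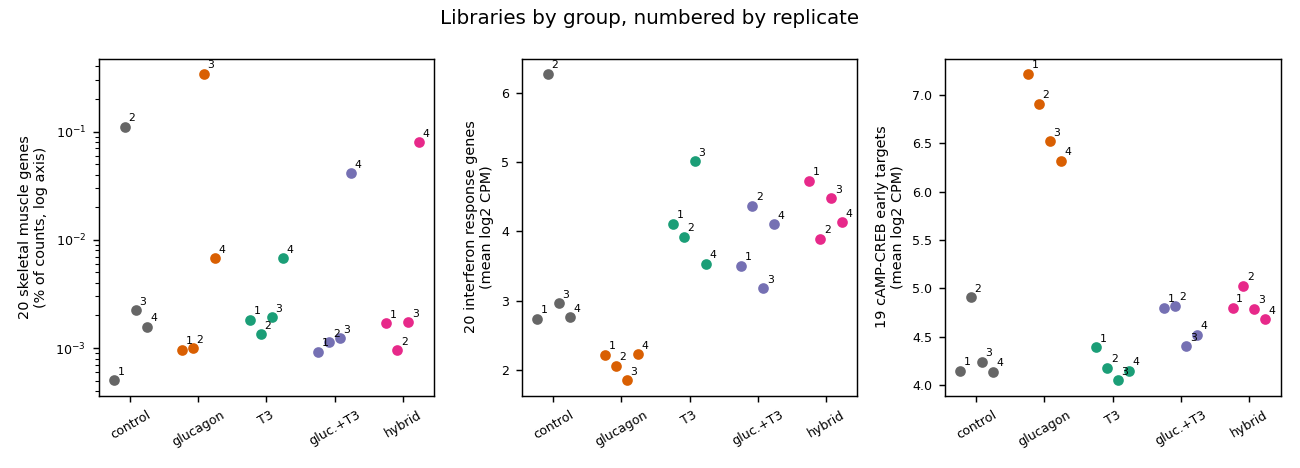
Values per library, with the groups in the same colours, for the share of counts in 20 skeletal muscle genes and for mean log2 CPM of gene lists. Control 2 stands apart with a mean of 6.27 log2 CPM over the interferon response genes, and glucagon 3 with 0.342% of its counts in muscle genes.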

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

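The tests below were chosen after the result was seen, namely all counts of other splits, the lane and clock tests of the cAMP-CREB pattern, both interferon tests and the count of muscle genes, while the library depth and exon length tests were set beforehand.

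Early target genes of cAMP-CREB stood higher after glucagon than after combination or hybrid. In each of lanes 1 to 4 the mean log2 CPM of the list was lower in combination and in hybrid than in the glucagon library of the same lane, by at least 1.63. Between lanes it differed by at most 0.9 within a group, which argues against the sequencing lane. With every library thinned to 6091917 counts its median change was 1.02 times the unthinned one (-2.10 against -2.06), which argues against depth. The 10 core clock output genes, a list written after the data were seen, changed less in combination against glucagon than in glucagon against control. Their median absolute change was 0.39 times as large (0.73 against 1.87). Of the 18 clock genes fixed beforehand, 7 were called lower and 3 higher in combination against glucagon with the lane as a block. A shift in clock phase is therefore not decided. An effect of T3 on the cAMP-CREB genes may be at work, a hypothesis found and tested on the same data. Clock phase, depth and unknown doses and times stay open.

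Interferon response genes were lower after glucagon than in control, 19 of 20 called. Without control 2, 4 of 20 were called, so control 2 alone may account for most of the pattern. Glucagon 3, which holds more muscle transcripts than control 2, had a mean -0.32 from the other glucagon libraries, but this is 1 library. Glucagon 3 also stood above the other glucagon libraries in blood, fat and pancreas genes (2.94 against -0.26 to 0.39). So it did in lymphocyte and granulocyte (2.38 against 1.15 to 1.63) and stellate cell and fibroblast genes (5.02 against 4 to 4.45), but not in cholangiocyte genes (2.82 against 2.36 to 2.85). Control 2 stood above the other controls in cholangiocyte (4.37 against 2.36 to 2.92), stellate cell and fibroblast (5.81 against 3.82 to 4.67) and lymphocyte and granulocyte genes (2.53 against 1.37 to 2.17). Other tissue carried along with the liver piece therefore cannot be told apart from a change in the liver of that mouse. Without control 2 the same genes rose in T3 (15), combination (8) and hybrid (17 of 20) against control, and an infection or other illness of that mouse was not tested. No biological explanation named by the design was tested for control 2.

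Skeletal muscle transcripts made up 0.111% of the counts in control 2 and 0.342% in glucagon 3. In both libraries 20 of 20 muscle genes stood over 4 times the median of the other 18 libraries, but the list was written after such transcripts were seen, so this count restates the pattern. Skeletal muscle carried along with the liver piece cannot be told apart from expression in these livers by it. Over 386 near-silent genes (median under 0.6 CPM, 86.8% with a length) the log ratio to the other libraries correlated with exon length with rho at most 0.10 (0.03 in glucagon 3). Symbols are listed only where some library reached 20 counts, and only the 20 listed muscle genes were left out. High values in these libraries can thus have chosen the genes, so genomic or unspliced RNA is not decided. The list itself had 0 genes called in 7 of the 9 comparisons and 1 lower in hybrid and in combination against glucagon (edgeR). No biological explanation was tested.

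Other splits of the compared libraries were counted, with the real one among them. For each comparison of single groups 1 of 35 splits gave as many called genes, the smallest share these splits allow. That is under 1 in 20 when lanes are ignored. It is not adjusted for the number of comparisons, so it argues against chance without excluding it. For hybrid against combination this rests on only 4 genes. In the 6 of these comparisons that lie within lanes, 8 of the splits keep 1 library of each group in each lane, too few for a share under 1 in 20. The highest other among those 8 was 654 for glucagon against control, 1 for combination against control and 0 in the other 4. The highest other splits were 654 genes against 2732 for glucagon against control, 506 against 2317 for T3, 309 against 2598 for combination and 768 against 3144 for hybrid. They were 0 against 4 for hybrid against combination (1 gene without hybrid 3 or hybrid 4), 1 against 3255 for hybrid against glucagon, 0 against 821 for hybrid against T3 and 0 against 2906 for combination against glucagon. For departure from additivity 5 of 100 random splits gave as many, up to 930 against 482. Those splits mix groups that differ in many genes (2732 for glucagon and 2317 for T3 against control), so they carry the single effects into the interaction and say nothing on chance for the 482. The 482 genes departing from additivity are themselves a difference between groups, tested as an interaction.

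Groups of 4 libraries were searched over the genes named in these texts, the muscle share, the total count and the number of genes at 0. In 43 of 840 such groups 1 library stood apart from the others by a share of the group's range beyond Dixon's limit, where chance gives about 1 in 20. That share is in brackets below, for genes on log2 CPM. For the muscle share of counts these were control 2 (0.984), glucagon 3 (0.983), T3 4 at 0.00678% (0.891), combination 4 at 0.0412% (0.992) and hybrid 4 at 0.0799% (0.99). In the combination group these were Gcgr in combination 3 at 438 CPM against 289 to 299 (0.923), Dio1 in combination 4 at 390 CPM against 489 to 511 (0.836) and Ndufv1 in combination 2 at 254 CPM against 225 to 230 (0.832). Further ones were Ccne1 in combination 1 at 12 CPM against 6.41 to 7.02 (0.856), Abcc3 in combination 3 at 22.9 CPM against 17.6 to 17.8 (0.959) and Chac1 in combination 3 at 5.83 CPM against 14.5 to 16.7 (0.863). A further one was Serpina3n in combination 3 at 550 CPM against 276 to 305 (0.855). In the hybrid group these were Gcgr in hybrid 2 at 145 CPM against 225 to 245 (0.835), Nr4a2 in hybrid 3 at 7.13 CPM against 5.22 to 5.41 (0.884) and Mpeg1 in hybrid 2 at 112 CPM against 90.8 to 93.7 (0.851). Further ones were Birc5 in hybrid 1 at 2.88 CPM against 8.93 to 9.52 (0.946) and Hsd3b7 in hybrid 2 at 194 CPM against 251 to 259 (0.898). In the T3 group these were Nr4a2 in T3 4 at 0.639 CPM against 1.3 to 1.44 (0.865), Ifi44 in T3 3 at 65.3 CPM against 19 to 22.8 (0.853) and Por in T3 3 at 593 CPM against 952 to 1030 (0.857). Further ones were Slc34a2 in T3 2 at 11.1 CPM against 8.73 to 9.07 (0.841), Mki67 in T3 3 at 50.5 CPM against 14 to 16.3 (0.881) and Lepr in T3 4 at 12.5 CPM against 6.42 to 6.99 (0.873). Further ones were Sik1 in T3 1 at 76.6 CPM against 144 to 156 (0.882), Cry2 in T3 3 at 47.4 CPM against 57.9 to 59.3 (0.893) and Arntl in T3 3 at 2.95 CPM against 5.37 to 6.01 (0.841). Further ones were Scd1 in T3 1 at 14200 CPM against 6320 to 6530 (0.96), Ddit4 in T3 3 at 21.4 CPM against 10.8 to 11.8 (0.87) and Ces4a in T3 1 at 33.8 CPM against 107 to 133 (0.838). Further ones were Mcm3 in T3 3 at 21.9 CPM against 10.5 to 10.9 (0.952), Stard4 in T3 2 at 36.6 CPM against 21.9 to 23.6 (0.853) and Oat in T3 3 at 134 CPM against 175 to 180 (0.905). In the control group these were Cyp17a1 in control 3 at 12.2 CPM against 32.5 to 38.3 (0.856), Dos in control 1 at 1.39 CPM against 6.13 to 7.06 (0.911) and Arhgef10l in control 3 at 50 CPM against 21.2 to 24 (0.859). Further ones were Akr1c6 in control 1 at 469 CPM against 100 to 115 (0.909), Tdo2 in control 1 at 535 CPM against 162 to 180 (0.915) and Manf in control 2 at 128 CPM against 65.2 to 72.7 (0.838). In the glucagon group these were Cyp17a1 in glucagon 2 at 30.8 CPM against 40.2 to 42.2 (0.842), Mt1 in glucagon 1 at 450 CPM against 269 to 290 (0.855) and Acly in glucagon 1 at 1930 CPM against 890 to 958 (0.905). Further ones were Nr0b2 in glucagon 2 at 7.37 CPM against 15.7 to 17.3 (0.885) and Srebf1 in glucagon 4 at 1410 CPM against 1360 to 1360 (0.847). No explanation was tested for these genes.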

How the results depend on the processing

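The fit without control 2 and glucagon 3 was chosen only after the results were seen, and its tests are named as such here. Counts of called genes stayed within 1.5 times under RLE factors, under no filter on low counts and with the replicate number as a block in all 9 comparisons. They did so with DESeq2 in 8 of them, where hybrid against combination rose from 4 to 28. A fit of the compared groups alone called 976 instead of 2732 for glucagon, 503 instead of 2317 for T3, 918 instead of 2598 for combination and 1208 instead of 3144 for hybrid against control. It called 16 instead of 4 for hybrid against combination and 1562 instead of 821 for hybrid against T3, and stayed within 1.5 times in the other 3. The common dispersion was 0.186 among the controls and 0.0356 to 0.0666 in the other groups, against 0.077 in the shared fit. The shared fit thus assumes less spread than the controls show, so its counts against control may be too high. How much of each change in count this accounts for was not tested. Without control 2 and glucagon 3 the counts were 2182, 2715, 2811 and 3681 for glucagon, T3, combination and hybrid against control, 3169 for hybrid and 2781 for combination against glucagon, and 525 for additivity.

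Leaving out 1 library at a time gave 1988 to 3760 genes for glucagon, 1528 to 3179 for T3, 1855 to 3552 for combination and 2333 to 3719 for hybrid against control. It gave 1 to 5 for hybrid against combination, 2627 to 2768 for hybrid against glucagon, 406 to 708 for hybrid against T3, 2264 to 2470 for combination against glucagon and 343 to 821 for additivity. Counts moved by over 1.5 times for T3 against control without T3 1 (1528), for hybrid against combination without hybrid 2 (2), hybrid 3 (1) or hybrid 4 (1), for hybrid against T3 without T3 1 (415), T3 2 (476), T3 4 (541), hybrid 2 (406) or hybrid 3 (468), and for additivity without control 3 (821). The cause was not tested.

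Of 78 list calls 4 held with an estimated correlation, all of the cAMP-CREB list, so single lists rest on the preset correlation. The planned fry test, which does not compare a list with other genes, called 8, 8, 4 and 7 lists for glucagon, T3, combination and hybrid against control, where camera called 7, 13, 6 and 7. It called 0 for hybrid against combination, 14 for hybrid against glucagon, 3 for hybrid against T3, 10 for combination against glucagon and 3 for additivity, where camera called 9, 14, 7, 9 and 6. With the block 79 were called. Without the 2 libraries 64 were called in 7 comparisons, with 6 lost and 8 gained. Gained were the lymphocyte and granulocyte list in 3 comparisons, as given in the report, and unfolded protein and integrated stress for glucagon against control (0.00151) and additivity (0.00998). The others were macrophages for combination against control (0.0104), cholesterol synthesis for hybrid against glucagon (0.033) and pericentral genes for additivity (0.0296). The correlation of the hybrid and combination effects was 0.894 with RLE factors too, and 0.508 with the controls split, where the effects share no controls.

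Across 4065 alternatives for 278 values of named genes, 0 turned direction with a call in the main fit or in the alternative. Turns between values not called were not counted. Of these alternatives 3922 kept their side of the threshold, 106 lost a call and 37 gained one. For 25 of the 278 values a call was lost somewhere, for 17 with 1 library left out. Lost and gained calls numbered 1 and 0 with RLE factors, 0 and 0 with no filter, 0 and 8 with DESeq2, 14 and 8 with the compared groups alone, 5 and 1 with the block, and 4 and 9 without the 2 libraries. The block changed no call besides those given in the report. RLE factors moved the median change of all genes by under 0.1 and the share of higher calls by under 10 points in each comparison.

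With 100 genes changed by log2 1 in simulated hybrid against control counts 49% were recovered. With the spread shared by the groups there, changes of that size were missed about as often as found. The wider spread of the controls was not part of that simulation. The T3 libraries, at 7021746 counts on average, measure genes of low level least well, and lane 5 cannot be separated from T3 for single genes.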

Other observations

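The counts of clock genes within lanes and the list of core clock output genes below are tests chosen only after the results were seen.

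Clock genes differed between the groups, though the circadian clock list was not called for any treatment against control (lowest camera adjusted p = 0.12, for glucagon). These genes were named after their values were seen. Cry1, a repressor of the clock, stood at 6.91 ± 3.39 CPM in control, 52.5 ± 7.3 after glucagon, 13.2 ± 2.45 after T3, 30.9 ± 4.47 after combination and 28.7 ± 3.25 after hybrid (log2 changes of 2.94, 2.18 and 2.07 for glucagon, combination and hybrid). Arntl, which encodes the clock activator BMAL1, stood at 7.31 ± 3.33, 40.5 ± 10, 5.02 ± 1.41, 27.1 ± 5.08 and 28 ± 3.55 CPM in the same order, and Nr1d1, a repressor of Arntl, at 218 ± 88.4, 37.1 ± 9.81, 123 ± 48.4, 51.2 ± 7.43 and 49.3 ± 6.83 CPM. Per2 and Nfil3 rose after glucagon by 2.62 and 2.51 and stood at 0.32 and -0.14 after combination and 0.14 and -0.02 after hybrid, against control.

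Of the 10 core clock output genes, 2 rose and 5 fell after glucagon, 2 and 1 after T3, 1 and 2 after combination and 1 and 2 after hybrid, each against control. Within lanes 6, 3 and 3 of the 10 were called after glucagon, combination and hybrid, and 5 went the same way in these 3 groups, 4 of them in the direction known for a shared phase. Times of tissue collection are not given in the sources used here, so a difference in time of day cannot be decided. This pattern was weighed first and was replaced by the interferon pattern above after its results were seen.

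The interferon response list had 18 genes higher in hybrid and 8 in combination against glucagon (19 and 19 without control 2 and glucagon 3), and 0 called between hybrid and combination, between hybrid and T3, and for additivity (edgeR).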
